A study of Homo sapiens with 6 samples.

How the data were processed

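RNA from K562, an established human line grown from chronic myeloid leukaemia, was hybridised to 1-colour Affymetrix arrays. Of 6 arrays, 3 came from cells given calactin, labelled 0.15 mM for 12 h, and 3 from untreated cells of the same time point. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made from 8 ug of it. The labels call the 3 samples of each group biological replicates.

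The deposited values are linear intensities, 1 per probe set and array, as the authors processed them. The summary algorithm, the background correction and any scaling to a common level are not given in the sources used here. The values themselves showed no quantile normalization, because the array medians ran from 31.2 to 34.4 and the 2% trimmed means from 228.6 to 257.8. Both were lower in every calactin array than in every untreated one. Medians were 31.2 to 32.1 with calactin and 33.1 to 34.4 in untreated arrays. Trimmed means were 228.6 to 237.1 and 249.0 to 257.8. The number of arrays limits the precision, with 4 residual degrees of freedom per gene before the variance is moderated.

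Of 54675 probe sets, 62 were array controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none in the platform annotation used here. Current symbols were found through the gene identifier for 41037 of the single-symbol probe sets, and this changed 0 symbols. No gene was named from a probe set with several symbols. The probe set with the highest mean over the 6 arrays stood for its gene, which left 19775 genes, 9252 of them with 1 probe set. For 62 genes, different probe sets were called in opposite directions. Of the genes set to be named in any case, 3 had no probe set with their symbol alone in that annotation and were not analysed here, among them HBG1, whose probe sets carry the symbol of HBG2 as well.

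Intensities were turned into log2(intensity + 16). A fold change below is on that scale and understates the change of dim genes. No further normalization was applied in the chosen setting. limma 3.58.1 (lmFit, eBayes with a variance trend) in R 4.3.3 compared calactin with untreated arrays, two-sided, and p-values were adjusted over all 19775 genes by the Benjamini-Hochberg method with a threshold of 0.05. A gene at an absolute log2 fold change of at least 1 was counted as changed at least 2-fold. A positive value is higher with calactin. Plots were drawn with matplotlib 3.10.9.

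For 35 gene lists, limma's camera with a preset inter-gene correlation of 0.01 compared the genes of a list with all others, and p-values were adjusted over the lists. The lists covered the sodium pump and ion transport, DNA damage, repair, replication and mitosis, histones and their modifying enzymes, cell death and stress responses, metabolism, RNA and protein synthesis, the blood lineages of K562, and markers of 4 other kinds of cell. A list needed at least 5 measured genes, and counts of members are of measured genes. Members past the threshold are counted over all genes tested and, where stated, adjusted over the list alone.

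The genes named were set by rule: the 12 largest rises and the 12 largest falls among called genes whose 3 calactin arrays all lay on 1 side of the 3 untreated arrays and whose brighter group lay above the median signal, up to 4 genes with the smallest p from each list, and ATP1B1, ATP1B3, H2AX, CDKN1A, MYC, FOS, EGR1 and CCNB1. The test, the lists, this rule and the alternatives below were chosen before the data were examined, except where the text says otherwise.

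Alternatives set beforehand were quantile normalization, median centring, a pseudocount of 1 or 64, genes above the median signal alone, the mean of a gene's probe sets, probe sets whose identifiers mark no shared sequence first, eBayes without a trend or with robust estimation, the replicate number as a block, each array left out in turn, every probe set tested on its own, and for the lists an estimated correlation or limma's fry. Chosen after seeing the data were replicates 1 and 2 alone, the split between replicate numbers seen in the poly-A spikes as a block, though the labels name no batch, scaling to the hybridisation spikes, with or without the replicate block, and scaling to the poly-A spikes with that block. The poly-A scaling was not run without the block, so poly-A spike scaling below always includes it. The robust setting has no counterpart in camera and was not run for the lists.

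Replicate numbers came from the sample titles. Over the 9887 genes above the median signal, the deviations of the calactin and the untreated array of a number from their group means correlated at 0.544, 0.409 and 0.345 for numbers 1, 2 and 3, and each array correlated best with its own number, the highest value with another number being -0.008. Deviations cancel within a group, so positive values with the own number push those with other numbers toward negative ones. The numbers were taken as pairing the samples, as a pattern found in the data that the labels do not state. The chosen fit did not use this pairing. With the replicate block, 1402 genes were higher and 3992 lower.

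The steps were tested on simulated data for 19775 genes in 3 against 3 arrays with known changes in 200 genes, all above the median signal. Noise was drawn independently for each gene and array, without correlation between genes and without pairing of replicates. Of 50 genes each, 26% were recovered at a log2 change of 0.5, 76% at 1, 96% at 2 and 16% at -0.5. Of the genes called, 5.31% had not been changed, and 0 genes were called where nothing had been changed. Camera gave an unadjusted p under 0.05 for 2.5% of 200 random lists. Because the simulated genes were not correlated, that share does not give the error of the lists on the real arrays. No pair of arrays held identical values.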

Results

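Gene expression was measured in K562, a human chronic myeloid leukaemia line that carries the BCR-ABL1 fusion. Cells had been exposed for 12 h to calactin, a cardenolide, at a dose the labels give as 0.15 mM. That unit is high for a cardenolide and rests on the labels alone. Cardenolides are plant steroids that inhibit the sodium pump. There were 3 calactin arrays and 3 arrays of untreated cells, and the number of arrays limits the precision. The median signal of an array was 31.2 to 32.1 intensity units with calactin and 33.1 to 34.4 in untreated arrays. Every calactin array thus lay below every untreated one. Correlations of the log2 signals were 0.989 to 0.992 between arrays of a group and 0.974 to 0.979 between the groups. The 1st principal component held 78.1% of the variance. The comparison asks which transcripts differ between exposed and untreated cells, and the title of the series names DNA damage and histone modification as its themes.

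The largest fall with calactin was that of EGR1. This gene, a transcription factor induced within minutes of growth signals, fell 23.2-fold, from a signal of 7012 ± 3596 to 257.2 ± 65.8 (mean ± SD, n = 3 each). CXCL8 and CXCL2, which encode chemokines that attract neutrophils, fell 12.7-fold and 9.84-fold. MYCL, a relative of MYC, fell 7.92-fold, and FOS, a partner of JUN in the AP-1 factor, fell 6.88-fold. The rises were smaller: G0S2, an inhibitor of the lipase ATGL, rose 4.35-fold, SOCS1, which restrains JAK kinases, rose 3.51-fold, and E2F1, a driver of entry into S phase, rose 3.28-fold.

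Among the other large falls were MYEOV at 13.6-fold, LCP2, an adaptor in immune receptor signalling, at 8.94-fold, and ZNF777 at 8.30-fold. HK2, the hexokinase that starts glycolysis, fell 6.61-fold, and MSMO1, an enzyme of cholesterol synthesis, fell 6.58-fold. NRROS fell 6.77-fold and C11orf96 7.53-fold. With the mean of a gene's probe sets, the log2 change was smaller for several of these genes, at -1.18 for LCP2, -1.39 for ZNF777 and -1.92 for MYCL. With probe sets of unshared sequence preferred, CXCL2 and C11orf96 were no longer called, and FOS was not called in replicates 1 and 2 alone. CPEB4, which binds the 3' ends of messenger RNAs, rose 3.80-fold, E2F8, an atypical E2F repressor, 3.50-fold, and EPAS1, the hypoxia factor HIF-2alpha, 3.29-fold. The calls of E2F8 and EPAS1 were lost in replicates 1 and 2 alone. TMEM79 rose 3.67-fold, ZNF335 3.44-fold, SLC6A9, a glycine transporter, 3.36-fold, RFX3 3.30-fold and PIK3R3, a regulatory subunit of PI3 kinase, 3.27-fold. With the mean of a gene's probe sets, SOCS1 was at 0.74 on the log2 scale, ZNF335 and RFX3 at 0.62 and EPAS1 at 0.83. The largest fitted rise, 5.53-fold for ARRDC4, an arrestin-related gene, was called in 14 of 21 alternatives. Untreated replicate 2 had an ARRDC4 signal of 1797 against 246.4 and 313.5 in the other untreated arrays, and the call was lost without any of calactin replicates 1, 2 and 3 and untreated replicates 1 and 3 (highest adjusted p = 0.222 over the alternatives).

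**Figure D1:**
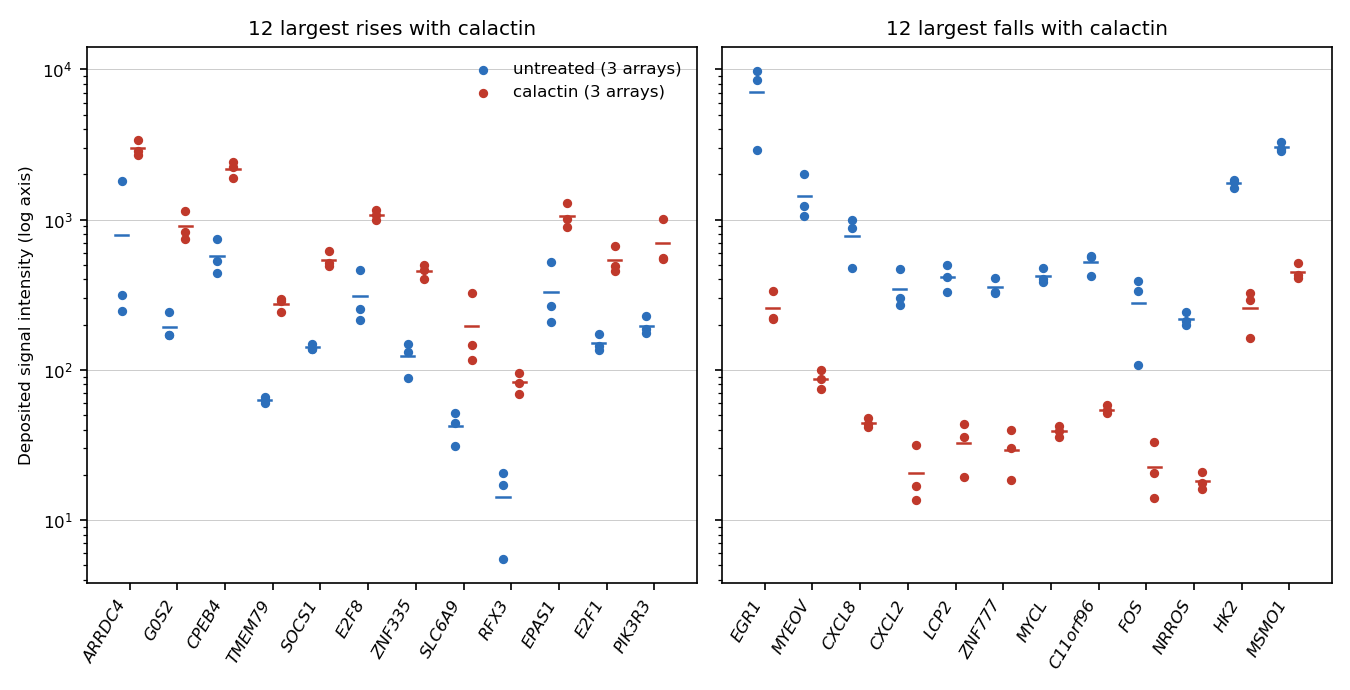
Deposited signal intensity on a log axis for the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array, 3 calactin and 3 untreated arrays, and a bar at each group's mean. EGR1 spans the widest distance, from a mean of 7012 in untreated to 257.2 in calactin arrays.

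Of 19775 genes tested with limma, 4239 were called, 975 higher and 3264 lower with calactin. At least 2-fold changes numbered 105 higher and 870 lower. The 3 arrays of a group all lay on 1 side of the other group's for 6860 genes, or 34.7% of all genes tested. Arrays in random order give 10% for a single gene. Genes share the same arrays, whose overall signal differed between the groups, so this share is no test of change gene by gene. The median of all genes was -0.06 on the log2 scale, and the median standard error was 0.16. Quantile normalization gave 1661 higher and 2401 lower genes, and scaling to the poly-A spikes with the replicate block gave 10719 higher and 1006 lower and moved the median of all genes to 0.50. Of the calls, 77.0% were lower on the deposited scale, 59.1% under quantile normalization, 69.2% under median centring, 69.1% under hybridisation spike scaling, 74.0% with the replicate block alone and 8.58% under poly-A spike scaling with that block. Without calactin replicate 2 there were 648 higher genes, and 644 without calactin replicate 3. Among genes described below, hybridisation spike scaling with the replicate block lost the calls of MYC, H2AX, H2BC11, H2AC8, MCM5, BUB1, BIRC5, MCL1, TXNIP, PHGDH, CTSB, SOCS2, TUBB6, ATP1B3, NDUFV2, UQCRC2, PSMD4, PSMA5, ISG15, CD3D, KRT18 and COL1A2. Poly-A spike scaling lost those of MYC, GATA1, BUB1, MCL1, TUBB6, KRT18 and COL1A2, and eBayes without a trend those of NDUFV2, UQCRC2, H2AC8, ATP1B3, PSMD4, PSMA5 and ISG15. Besides losses given with the genes, replicates 1 and 2 alone lost those of MYC, H2BC11, H2AC8, SQSTM1, NDUFV2, UQCRC2, PSMD4, PSMA5, ISG15, CD3D and COL1A2.

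The probe sets of a gene did not always move alike. With their mean, 39 of 127 called named genes had a log2 change smaller by over 1.5 times. Besides those given elsewhere, they included, among falls, CXCL2 (-1.18), C11orf96 (-1.55), PFKP (-0.87), PDK1 (-0.88), SRSF5 (-0.87), SRSF6 (-0.81), TRIB1 (-0.73), TNFRSF10B (-0.69), EHMT2 (-0.43), CFLAR (-0.46), PRF1 (-0.97), APAF1 (-0.46), BRD3 (-0.55), RNF8 (-0.61), COL1A2 (-0.43), BUB1 (-0.12), UQCRC2 (-0.14) and PSMD4 (-0.12). Among rises they included CLK4 (0.66), KMT2A (0.45), CREBBP (0.48), NFAT5 (0.67), SLC5A3 (0.35), ATP2B1 (0.56) and SQSTM1 (0.32); the calls of BUB1, UQCRC2, PSMD4, PSMA5 and SQSTM1 were lost. A pseudocount of 64 gave RFX3 0.90, NRROS -1.77, FOSB -0.85 and TUBB2B -0.90.

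Genes of cholesterol synthesis and of glycolysis fell as groups. Of 17 cholesterol genes, 12 fell, 1 rose and 4 were not called, with the same counts adjusted over the list alone; the median was -0.89 (adjusted p = 4.04e-06; adjusted p = 0.42 with an estimated correlation). Over the alternatives the cholesterol median ran from -1.02 to -0.33. SQLE, which oxidises squalene, fell by 1.66 ± 0.09 (log2, SE, n = 3 each), NSDHL by 1.72 ± 0.12 and INSIG1, the sterol sensor's anchor, by 1.58 ± 0.11. Of 30 genes of glycolysis and the hypoxia response, 13 fell, 1 rose and 16 were not called, the same counts adjusted over the list alone. Their median was -0.19 (adjusted p = 0.00112, and 0.42 with an estimated correlation), and 0.37 under poly-A spike scaling. The latter lay below the median of all genes there, and camera still called this list (adjusted p = 3.63e-05). PFKP, a phosphofructokinase, fell by 1.94 ± 0.10, PFKFB4 fell by 1.70 ± 0.11 and PDK1, which inhibits pyruvate dehydrogenase, fell by 1.52 ± 0.12. Of 31 genes of oxidative phosphorylation, 2 fell, NDUFV2 and UQCRC2, both of which had the other sign under poly-A spike scaling, and 1 fell adjusted over the list alone (median -0.02, 0.54 under poly-A spike scaling; adjusted p = 0.619). The UQCRC2 call was lost without calactin replicate 2 or 3 or untreated replicate 1 or 3, with a highest adjusted p of 0.949 over the alternatives.

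Genes that build ribosomes fell. Of 28 ribosome biogenesis genes, 15 fell and 0 rose, and 17 fell adjusted over the list alone. Their median was -0.50 (adjusted p = 1.18e-06, and 0.42 with an estimated correlation), and 0.06 under poly-A spike scaling. The latter lay below the median of all genes there, and camera still called the list (adjusted p = 1.78e-05). NOB1, an endonuclease that finishes the small subunit's RNA, fell by 1.52 ± 0.08, TSR1 by 1.21 ± 0.09, LYAR by 1.37 ± 0.11 and RRS1 by 1.52 ± 0.13. MYC, which drives many of these genes, fell by 0.70 ± 0.16 and was called in 15 of 21 alternatives; the call was lost without calactin replicate 3, untreated replicate 1 or untreated replicate 3. Of 43 cytosolic ribosomal protein genes, 0 were called over all genes or adjusted over the list alone by limma, and 0 had an unadjusted p under 0.05 (median -0.03, 0.53 under poly-A spike scaling; list adjusted p = 0.99). Their median signal was 13953, where the highest signal of any array was 19310, and RPLP2 lay near background, so these counts do not show that the genes stayed level. Of 31 translation factor genes, 12 fell and 1 rose, and 13 and 1 adjusted over the list alone, with a median of -0.16 that was 0.40 under poly-A spike scaling (adjusted p = 0.0235; adjusted p = 0.496 with an estimated correlation). That list was called in 15 of 22 alternatives (range 0.0027 to 0.496). Its call was also lost under median centring (adjusted p = 0.0538), with genes above the median signal alone (0.246), with eBayes without a trend (0.0718) and under hybridisation spike scaling without and with the replicate block (0.176 and 0.232), and under poly-A spike scaling, where its median changed sign (0.365). EIF5, which triggers GTP hydrolysis at the start codon, fell by 1.63 ± 0.16, and EEF2K, the kinase that slows elongation, by 1.14 ± 0.09.

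Among 32 splicing factor genes, 6 rose and 9 fell, and 6 and 10 adjusted over the list alone (median -0.05, 0.51 under poly-A spike scaling; adjusted p = 0.99). CLK1 and CLK4, kinases of SR proteins, rose by 1.59 ± 0.12 and 1.55 ± 0.15, while the SR protein genes SRSF5 and SRSF6 fell by 1.72 ± 0.10 and 1.31 ± 0.12. Of 3 SRSF5 probe sets, 2 were called lower and 1 higher. Of 28 proteasome genes, 7 fell and 0 rose, also adjusted over the list alone (median -0.06, 0.50 under poly-A spike scaling; adjusted p = 0.672). PSMD4 fell by 0.28 ± 0.06 and PSMA5 by 0.33 ± 0.08, both of which were positive under poly-A spike scaling, and PSMD4 was also positive, at 0.33, with probe sets of unshared sequence preferred. The call of PSMA5 was lost without calactin replicate 1 and without untreated replicate 3.

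DNA repair genes fell as a group. Of 40, 20 fell, 2 rose and 18 were not called, with 23 lower and 6 higher adjusted over the list alone. The median was -0.43 (adjusted p = 4.29e-04, and 0.42 with an estimated correlation), and 0.13 under poly-A spike scaling. That value lay below the median of all genes there, and camera still called the list (adjusted p = 0.00898). FANCF and FANCL, of the Fanconi pathway for crosslinks, fell by 1.83 ± 0.14 and 1.21 ± 0.11, and XPC and ERCC5, of nucleotide excision repair, by 1.28 ± 0.10 and 1.39 ± 0.13. Of 28 genes of DNA damage signalling, 8 rose and 11 fell, and 8 and 13 adjusted over the list alone (median -0.15, 0.41 under poly-A spike scaling; adjusted p = 0.99). H2AX, whose protein is phosphorylated at DNA breaks, rose by 0.52 ± 0.07, and CDC25A, a phosphatase that activates cyclin kinases, by 0.97 ± 0.12, while RNF8, a ubiquitin ligase at breaks, fell by 1.09 ± 0.15. Of 27 p53 targets, 6 rose and 5 fell, and 6 and 7 adjusted over the list alone (median -0.05, 0.51 under poly-A spike scaling; adjusted p = 0.858). CDKN1A, the cyclin kinase inhibitor p21, was not called, at -0.29 ± 0.21 (adjusted p = 0.444). PMAIP1, a BH3-only gene, rose by 0.64 ± 0.11, and TNFRSF10B, a death receptor, fell by 1.11 ± 0.13.

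Mitotic and core histone genes rose as groups. Of 40 mitotic genes, 12 rose and 3 fell, and 13 and 4 adjusted over the list alone, with a median of 0.14 (adjusted p = 5.12e-05; adjusted p = 0.496 with an estimated correlation). FOXM1, a factor for mitotic genes, rose by 0.65 ± 0.09 and ANLN, of the cleavage furrow, by 0.82 ± 0.11, while BUB1, a checkpoint kinase, fell by 0.60 ± 0.07, a call lost with the mean of its probe sets. CCNB1, the mitotic cyclin B1, was not called, at 0.10 ± 0.07 (adjusted p = 0.37). Of 28 core histone genes, 5 rose and 0 fell, also adjusted over the list alone. Their median was 0.20 (adjusted p = 1.07e-04, and 0.42 with an estimated correlation). No control shows which part of the RNA was labelled, and the middle control probe set of 28S ribosomal RNA also rose with calactin. A change in labelling and a change in histone transcript levels were therefore not told apart. H2BC11 rose by 0.52 ± 0.11 and H2AC8 by 0.44 ± 0.11, the latter called in 13 of 21 alternatives. The H2BC11 call was lost without calactin replicate 3, and the H2AC8 call without calactin replicate 1 or 3 or untreated replicate 1 or 3. Of 42 genes of DNA replication, 6 rose and 5 fell, and 9 and 8 adjusted over the list alone (median 0.03, adjusted p = 0.0745). The list was called without calactin replicate 1 (adjusted p = 0.0215) and without calactin replicate 3 (adjusted p = 0.0255), and in 7 of 22 alternatives in all, within a range of 9.55e-04 to 0.803. E2F2 rose by 1.04 ± 0.11 and MCM5, of the replicative helicase, by 0.57 ± 0.09, while PRIM1, the primase, fell by 1.32 ± 0.09.

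Enzymes that modify histones went both ways. Of 29 genes of histone acetylation, 6 rose and 7 fell, and 7 and 7 adjusted over the list alone (median -0.01, 0.55 under poly-A spike scaling; adjusted p = 0.456). The acetyltransferase genes KAT2B, CREBBP and KAT6A rose by 1.10 ± 0.17, 0.88 ± 0.12 and 0.85 ± 0.09, and BRD3, a reader of acetylated histones, fell by 1.13 ± 0.13. Of 42 genes of histone methylation and histone kinases, 8 rose and 12 fell, and 9 and 13 adjusted over the list alone (median 0.04, adjusted p = 0.411). KMT2A, a methyltransferase for histone H3 lysine 4, rose by 1.16 ± 0.13, though of its 11 probe sets 5 were called higher and 1 lower, and the demethylase gene KDM6A by 0.82 ± 0.09, a call lost with probe sets of unshared sequence preferred. EHMT2, a methyltransferase for lysine 9, fell by 0.91 ± 0.10, and KDM2B, a demethylase, by 1.03 ± 0.09.

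**Figure D2:**
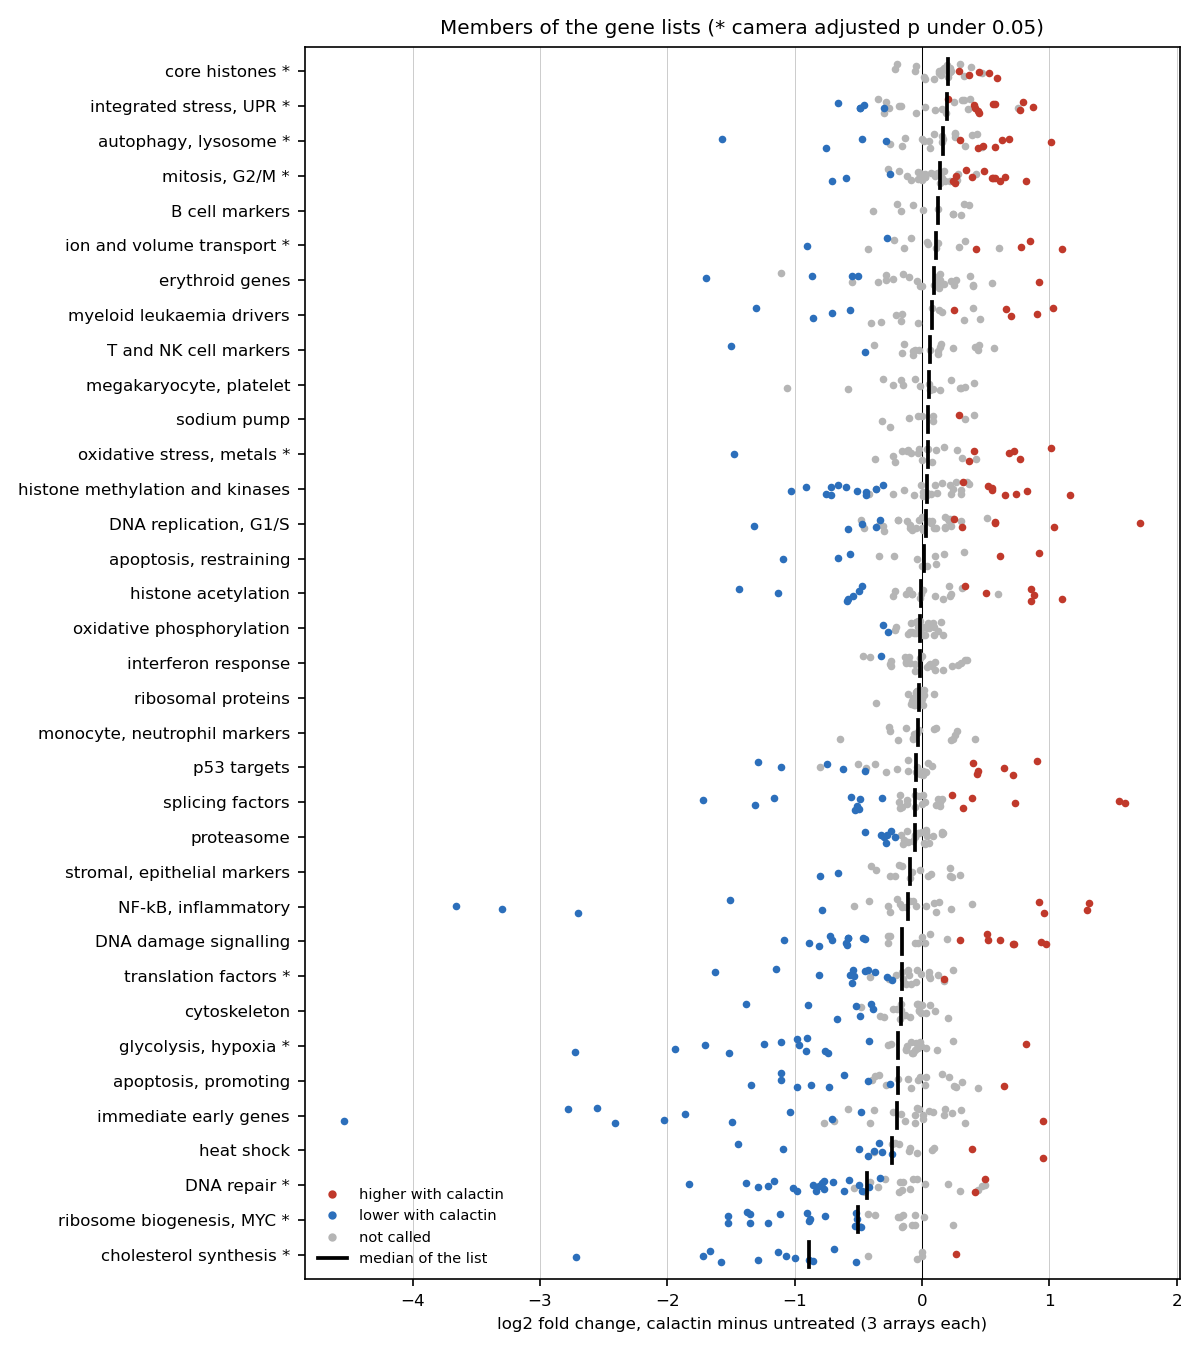
Log2 fold change (calactin minus untreated, 3 arrays each) of every measured member of the 35 lists, with 1 point per gene, coloured by its call, and a bar at the list's median. Cholesterol synthesis has the lowest median, -0.89, and 11 lists were called by camera with the preset correlation. Of the 5 called lists with a median below 0, all but cholesterol synthesis have a median above 0 under poly-A spike scaling, though below that of all genes there.

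Among the called members of the immediate early list, falls outnumbered rises, but most members and the list itself were not called by the chosen tests. Of 32, 10 fell and 1 rose, and 12 and 1 adjusted over the list alone (median -0.20, 0.36 under poly-A spike scaling; adjusted p = 0.0513). FOSL1 and FOSB, relatives of FOS, fell by 2.41 ± 0.17 and 1.86 ± 0.15, and TRIB1, a pseudokinase, by 2.02 ± 0.16. The list was called without calactin replicate 3 (adjusted p = 0.0311) and without untreated replicate 2 (adjusted p = 0.013), and in 11 of 22 alternatives in all, within a range of 3.13e-08 to 0.496. Of 26 NF-kB and inflammatory genes, 4 rose and 5 fell, and 5 and 5 adjusted over the list alone (median -0.11, 0.45 under poly-A spike scaling; adjusted p = 0.99). CXCL3, a chemokine gene, fell by 2.70 ± 0.19, while REL, a subunit of NF-kB, rose by 1.29 ± 0.09.

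Stress responses were mixed. Of 32 genes of the integrated stress and unfolded protein responses, 10 rose and 5 fell, and 14 and 7 adjusted over the list alone (median 0.19, adjusted p = 0.0148; adjusted p = 0.583 with an estimated correlation). SLC3A2, a subunit of amino acid exchangers, rose by 0.87 ± 0.11, PPP1R15A, which directs eIF2alpha dephosphorylation, by 0.79 ± 0.11, and PHGDH, of serine synthesis, by 0.58 ± 0.09. With the mean of a gene's probe sets, the list's median was -0.006 and its call was lost, as it was with probe sets of unshared sequence preferred; it was called in 18 of 22 alternatives. Of 29 autophagy and lysosome genes, 7 rose and 4 fell, and 12 and 5 adjusted over the list alone (median 0.17, adjusted p = 0.00348; adjusted p = 0.496 with an estimated correlation). CTSB, a lysosomal protease, rose by 0.44 ± 0.07, a call lost with the mean of its probe sets, at 0.13, and WIPI1, of the forming autophagosome, fell by 1.57 ± 0.20. Of 25 genes of oxidative stress and metals, 6 rose and 1 fell, and 6 and 2 adjusted over the list alone (median 0.04, adjusted p = 0.0257; adjusted p = 0.633 with an estimated correlation). TXNIP, an inhibitor of thioredoxin, rose by 0.68 ± 0.06, and SRXN1, sulfiredoxin, fell by 1.48 ± 0.15. That list's call was lost without calactin replicate 2 (adjusted p = 0.0994), untreated replicate 1 (adjusted p = 0.106) or untreated replicate 3 (adjusted p = 0.0593), and it was called in 14 of 22 alternatives, within a range of 0.00162 to 0.633; with probe sets of unshared sequence preferred its median was -0.02. SQSTM1, the autophagy receptor p62, rose by 1.01 ± 0.16, but was at -0.02 with probe sets of unshared sequence preferred.

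Of 19 heat shock genes, 2 rose and 8 fell, also adjusted over the list alone (median -0.24, 0.32 under poly-A spike scaling; adjusted p = 0.0927). DNAJB1, a co-chaperone, fell by 1.09 ± 0.09 and DNAJB4 rose by 0.95 ± 0.10. Without untreated replicate 2 the heat shock list was called (adjusted p = 0.0418, range 0.00931 to 0.967 over 22 alternatives, of which 3 called it). Of 27 genes that promote apoptosis, 9 fell and 1 rose, also adjusted over the list alone (median -0.19, 0.37 under poly-A spike scaling; adjusted p = 0.27). FADD, the death receptor adaptor, fell by 1.34 ± 0.13, APAF1, the scaffold of the apoptosome, by 1.10 ± 0.13 and BNIP3 by 0.98 ± 0.09. Of 15 genes that restrain it, 2 rose and 3 fell, also adjusted over the list alone (median 0.02, adjusted p = 0.606). BIRC5, survivin, rose by 0.61 ± 0.07 and TNFAIP3 by 0.92 ± 0.12, while MCL1, a BCL2 relative, fell by 0.66 ± 0.10 and CFLAR, which blocks caspase 8, by 1.09 ± 0.10. With probe sets of unshared sequence preferred, neither MCL1 nor CFLAR was called, and MCL1 was at -0.03.

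Of 14 sodium pump genes listed, 10 were measured, those of the beta subunits and of FXYD proteins alone; of these 1 rose and 0 fell, also adjusted over the list alone (median 0.05, adjusted p = 0.356). ATP1B3, a beta subunit of the pump, rose by 0.29 ± 0.06 (adjusted p = 0.0114), a call that was lost without calactin replicate 2 and a direction that turned to -0.03 with the mean of its probe sets. ATP1B1, another beta subunit, was not called, at 0.34 ± 0.21. Of 17 genes of ion and volume transport, 4 rose and 2 fell, and 5 and 2 adjusted over the list alone (median 0.11, adjusted p = 0.0252; adjusted p = 0.42 with an estimated correlation). NFAT5, the transcription factor of the response to hypertonicity, rose by 1.10 ± 0.12 and SLC5A3, a sodium and inositol carrier that it drives, by 0.77 ± 0.09. ATP2B1 rose by 0.84 ± 0.10 and ATP2B4 fell by 0.91 ± 0.11; both encode calcium pumps of the cell membrane. With probe sets of unshared sequence preferred, ATP2B1 was at 0.03 and not called. Without untreated replicate 3 the list's call was lost (adjusted p = 0.0555, range 0.00283 to 0.42 over 22 alternatives, of which 18 called it), as it was with the mean of a gene's probe sets and with probe sets of unshared sequence preferred. Of 28 cytoskeleton genes, 7 fell and 0 rose, also adjusted over the list alone (median -0.17, 0.39 under poly-A spike scaling; adjusted p = 0.0513). TUBB6 and TUBB2B, beta tubulins, fell by 0.89 ± 0.07 and 1.38 ± 0.15. The cytoskeleton list was called with the replicate block (adjusted p = 0.0291), without calactin replicate 1 (adjusted p = 0.0201), untreated replicate 2 (adjusted p = 0.0418) and untreated replicate 3 (adjusted p = 0.0358), and in 6 of 22 alternatives in all, within a range of 0.00577 to 0.569.

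Of 31 erythroid genes, 1 rose and 4 fell, also adjusted over the list alone (median 0.10, adjusted p = 0.619). GATA1, the master factor of the lineage, fell by 0.86 ± 0.17 and LMO2, its partner, by 1.69 ± 0.18, while TAL1, another partner, rose by 0.92 ± 0.10. With probe sets of unshared sequence preferred, neither LMO2 nor TAL1 was called, and TAL1 was at -0.03. Of 21 myeloid leukaemia genes, 5 rose and 4 fell, and 6 and 6 adjusted over the list alone (median 0.08, adjusted p = 0.27). STAT5A, a factor activated by BCR-ABL1, fell by 1.31 ± 0.17, while SOCS2, a target of STAT5, rose by 0.66 ± 0.08 and BCL6, a repressor, by 1.03 ± 0.14, a call lost in replicates 1 and 2 alone. Of 17 megakaryocyte and platelet genes, 0 were called by limma over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05 (median 0.05, adjusted p = 0.526). TUBB1, a platelet beta tubulin, was not called, at -1.06 ± 0.43 (adjusted p = 0.132), but was called with the replicate block (adjusted p = 9.54e-04, range 3.67e-04 to 0.356 over the alternatives). Of 27 interferon response genes, 1 fell, ISG15, called in 7 of 21 alternatives and not when any 1 array was left out, and 0 were called adjusted over the list alone by limma, where 4 had an unadjusted p under 0.05 (median -0.02, 0.54 under poly-A spike scaling; adjusted p = 0.619).

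Markers of other cells were included for comparison and are not a background without signal. In untreated arrays the median signal was 17.4 for T and NK cell markers and 55.2 for stromal and epithelial markers. Single members lay far higher, such as KRT18 at 7335 and CD3D at 2330. Of 19 T and NK cell markers, 2 fell, PRF1 and CD3D, also adjusted over the list alone (median 0.06, adjusted p = 0.526). PRF1, perforin, fell 2.83-fold, and CD3D fell by 0.45 ± 0.09 but was at 0.11 under poly-A spike scaling. Of 11 B cell markers and of 17 monocyte and neutrophil markers, 0 each were called over all genes or adjusted over the list alone by limma, and 1 and 3 had an unadjusted p under 0.05 (medians 0.12 and -0.04, the latter 0.52 under poly-A spike scaling; adjusted p = 0.359 and 0.526). Of 17 stromal and epithelial markers, 2 fell, KRT18 and COL1A2, also adjusted over the list alone (median -0.09, 0.47 under poly-A spike scaling; adjusted p = 0.858). KRT18 fell by 0.66 ± 0.10, and COL1A2 by 0.80 ± 0.17 but was at 0.003 with probe sets of unshared sequence preferred.

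In all, 11 of the 35 lists were called, 6 up and 5 down, and 0 were called with an estimated correlation, where the smallest adjusted p was 0.42. The medians of the 6 lists called up moved too. Over the alternatives they reached 0.70 for mitosis, 0.76 for core histones, 0.75 for integrated stress, 0.73 for autophagy, 0.67 for ion transport and 0.60 for oxidative stress. Poly-A spike scaling put the median of all genes at 0.50. With fry, the calls of the mitosis, integrated stress, oxidative stress and autophagy lists were lost, and the immediate early, apoptosis-promoting, heat shock, cytoskeleton and NF-kB lists were called. Median, mean and test differed in sign for 11 lists, none of them called by camera with the preset correlation in the chosen setting: p53 targets, histone acetylation, histone methylation, genes that restrain apoptosis, erythroid, megakaryocyte, NF-kB, interferon, oxidative phosphorylation, T and NK cell markers, and monocyte markers. Of these, NF-kB was called with fry, and histone acetylation and histone methylation under poly-A spike scaling. With the replicate block, which called 1402 genes higher and 3992 lower, some counts of called members moved by over 1.5 times. Erythroid genes then numbered 7 higher and 7 lower, replication genes 11 and 9, autophagy genes 12 and 5, core histone genes 7 and 1, cytoskeleton genes 0 and 11, and stromal and epithelial markers 0 and 5. Higher members numbered 5 for DNA repair, 4 for genes that promote apoptosis, 3 for immediate early genes, 2 for glycolysis and 2 for translation factors. Oxidative phosphorylation had 1 higher and 4 lower, interferon 0 and 3, oxidative stress 8 and 2, the sodium pump 1 and 1 and megakaryocyte genes 0 and 1, while ribosomal protein genes and the B cell and monocyte markers had 0.

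Control transcripts gave signs of RNA quality and of labelling. The log2 ratio of the 3' to the 5' probe set differed between the groups by -0.05 for ACTB and 0.02 for GAPDH (exact two-sided permutation p = 0.6 for each, n = 3; the smallest possible is 0.1). These probe sets lay at 10087 to 14467, near the top of the signal range, where a ratio can hardly move. For the dimmer ISGF3A control transcript, at 123.5 to 858.7, the difference was -0.02 ± 0.22 (SE; exact p = 0.9). The poly-A spikes, bacterial transcripts usually added before labelling, were 11.3-fold higher in replicates 1 and 2 than in replicate 3 of both groups. Calactin minus untreated, they differed by -0.55, -0.75 and -0.38 (log2) in replicates 1, 2 and 3, with a mean of -0.56 ± 0.11 (SE). The hybridisation spikes differed by -0.43, -0.11 and 0.22. Replicates 1 and 2 alone called 332 genes higher and 1403 lower, and 99.3% of these 1735 genes had the same sign in replicate 3.

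**Figure D3:**
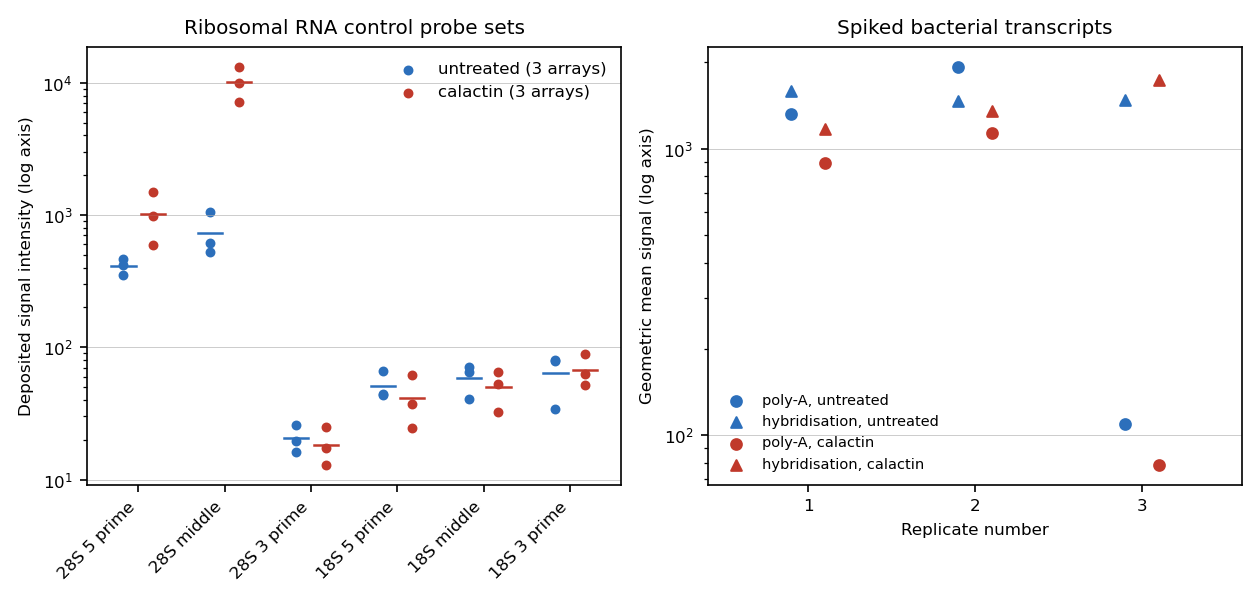
Left, deposited signal intensity on a log axis of the ribosomal RNA control probe sets, with 1 point per array (3 per group) and a bar at the mean; right, geometric mean signal on a log axis of the poly-A and hybridisation spikes by replicate number. The middle 28S probe set averaged 10109 with calactin and 732.2 in untreated arrays, and the poly-A spikes were 11.3-fold higher in replicates 1 and 2 than in replicate 3.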

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

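The tests of the 28S pattern were chosen after the result was seen; the counts over splits of the arrays were planned.

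Among the 62 array control probe sets, which the comparison of genes does not use, 2 of the 3 for 28S ribosomal RNA, the middle and the 5' one, stood above the untreated level. The middle 28S probe set had a signal of 10109 ± 3027 with calactin and 732.2 ± 279.6 in untreated cells (mean ± SD, n = 3 each). Its mean log2 difference was 3.78, and the ratio of its mean signals was 13.8. For the 5' probe set the log2 difference was 1.18 and the ratio of mean signals 2.46. The exact permutation p of the log2 difference was 0.1 for both, the smallest possible. With calactin the middle probe set lay near the top of the signal range, so its rise may be understated. The 3' probe set of 28S was at 18.4 and 20.5, and the 18S probe sets lay between 41.4 and 67.5 in both groups.

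For this 28S pattern, 3 technical explanations were considered. The tables argue against a loss of RNA integrity and a larger share of all ribosomal RNA, as tested. The last, a batch, is answered by the design only where it follows the poly-A spike level. A loss of RNA integrity that doubles 3' to 5' ratios would raise that of the ISGF3A control transcript by at least 1 on the log2 scale, but its difference between the groups was -0.019 ± 0.22 (SE, n = 3 each). A smaller loss stays open, and ACTB and GAPDH lie too near the top of the signal range to show it. A larger share of all ribosomal RNA would raise the middle and the 5' probe set by the same factor, but the middle one rose by 2.60 ± 0.23 more (log2, SE, n = 3 each). The factors would be equal only if 366.9 of the 414.2 units of the untreated 5' signal were background. The labels name no batch. One that follows the poly-A spike level parts replicates 1 and 2 from replicate 3. Each replicate number holds 1 array of each group, so such a batch could not by itself raise 1 group. A processing step done apart for calactin and untreated samples could not be told apart from calactin and stays open. The mean difference within a replicate number equals that between the groups by construction, so it tests no batch. It was 3.78 ± 0.11 for the middle probe set (at least 3.63 in each number) and 1.18 ± 0.27 for the 5' one (0.71 in replicate 3). Tailing or cleavage of 28S RNA may be a biological source; it was not tested, and no control shows which part of the RNA was labelled.

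The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4239 genes, 975 of them at least 2-fold, and the highest of the other splits called 0 for both. It called 11 lists, against at most 8 in the others. Every other split mixes calactin and untreated arrays within its groups. A difference between calactin and untreated then adds to the residual variance, so few called genes are likely there in advance. The replicate numbers were taken as pairing the samples, a pattern found in the data. Among the 3 other splits that part all 3 pairs the highest number of lists was 4, and among the 6 that part 1 pair it was 8.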

How the results depend on the processing

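The alternatives with replicates 1 and 2 alone, the poly-A batch block and the spike scalings were chosen after the result was seen; the others were planned. Over all alternatives, 101 of 132 counts stayed within 1.5 times the reported one. Of 3281 values of named genes, 3028 kept direction and call, 165 lost the call, 48 gained one, 25 reversed and 15, uncalled both ways, changed sign. Of 766 list values the numbers were 617, 29, 28, 9 and 83. Of 127 called named genes, 75 were called in every alternative and 109 kept their sign in all. A spike scaling adds 1 shared error per array to every gene, and its small p-values rest on 3 replicate numbers. Robust eBayes was not run for lists, and 31 lists had enough genes above the median signal. Signal over background limits dim genes, for which the pseudocount sets the fold. Except where stated, the cause was not tested.

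Quantile normalization gave 1661 higher genes, 200 at 2-fold, and called immediate early (-0.13) and DNA replication genes (0.14). Median centring called the same lists (-0.14 and 0.087) and lost translation factors (-0.10). A pseudocount of 1 gave 172 higher genes at 2-fold; 64 shrinks dim folds by construction and gave 574 at 2-fold, 503 lower, and called immediate early (-0.13) and cytoskeleton genes (-0.16). Genes above the median signal called replication (0.03) and lost translation factors (-0.16), which eBayes without trend also lost (-0.16).

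The mean of a gene's probe sets shrank 39 of 127 called named genes by over 1.5 times and gave 623 genes at 2-fold, 46 higher and 577 lower; ATP1B3 reversed (-0.032), ion transport was lost (0.045), integrated stress reversed (-0.006) and heat shock was called (-0.28). Probe sets of unshared sequence reversed TPM1 (0.014), SQSTM1 (-0.024), TAL1 (-0.03), COL1A2 (0.003), PSMD4 (0.33) and oxidative stress (-0.024), lost ion transport (0.045) and integrated stress (0.13) and called immediate early genes (-0.30). Every probe set tested on its own, a larger number of tests, called 7611, 2011 higher and 5600 lower, with 1875 at 2-fold, 308 higher and 1567 lower.

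The replicate block called the cytoskeleton list (-0.17) and EPCAM, KRT19, NDUFB8, NDUFS1, FXYD5, BST2, IFITM1 and TUBB1, and changed no other call of a list or named gene. Replicates 1 and 2, with fewer samples, gave 1735 genes, 332 higher and 1403 lower, called immediate early (-0.25) and replication genes (0.081) and lost oxidative stress (0.063).

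Poly-A spike scaling with the replicate block gave 11725 genes, 10719 higher and 1006 lower, with 1152 higher and 209 lower at 2-fold, and moved the median of all genes to 0.50; the block alone called 5394 and left it at -0.06. It reversed EIF3D (0.028), VCL (0.042), TPM1 (0.075), HSPB1 (0.14), CD3D (0.11), TFRC (0.006), PDIA4 (0.10), EPCAM (0.35), NDUFV2 (0.26), UQCRC2 (0.29), NDUFB8 (0.36), NDUFS1 (0.35), PSMD4 (0.28), PSMD12 (0.11), PSMA5 (0.23), PSMC2 (0.32), ISG15 (0.24), LYZ (0.31) and RPL24 (0.47). Of 127 called named genes, 55 had a log2 change smaller by over 1.5 times or of the other sign, and 34 a larger one by over 1.5 times. Poly-A spike scaling also changed the sign of the medians of immediate early (0.36), DNA repair (0.13), histone acetylation (0.55), glycolysis (0.37), ribosome biogenesis (0.056) and translation factor genes (0.40). It called replication (0.59) and histone methylation (0.59). The scaling moved all genes, and camera compares a list with the others. DNA repair (adjusted p = 0.00898), glycolysis (3.63e-05) and ribosome biogenesis (1.78e-05) stayed called by camera there, with medians below that of all genes. Hybridisation spike scaling, with a median of all genes of 0.05, gave 2204 genes, 1523 lower, and 174 higher at 2-fold; with the replicate block it gave 1499, 386 higher and 1113 lower, and 174. Both called immediate early genes (-0.094) and lost translation factors (-0.052), and the block lost oxidative stress (0.15).

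An estimated correlation lost all 11 called lists: ion transport (0.11), DNA repair (-0.43), mitosis (0.14), core histones (0.20), integrated stress (0.19), oxidative stress (0.044), cholesterol (-0.89), glycolysis (-0.19), ribosome biogenesis (-0.50), translation (-0.16) and autophagy (0.17). With fry, which does not compare a list with other genes, immediate early (-0.20), apoptosis-promoting (-0.19), heat shock (-0.24) and cytoskeleton (-0.17) were called, NF-kB was called downward (-0.11), and mitosis (0.14), integrated stress (0.19), oxidative stress (0.044) and autophagy (0.17) were lost.

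Leaving out 1 array gave 644 to 1015 higher genes, the lowest without calactin replicate 3 and 648 without calactin replicate 2. List medians ran from 0.015 to 0.16 for ion transport (lost at 0.076 without untreated replicate 3), -0.29 to -0.19 for immediate early (called at -0.20 without calactin replicate 3 and -0.28 without untreated replicate 2) and -0.025 to 0.076 for replication (called at 0.067 without calactin replicate 1 and 0.076 without calactin replicate 3). They ran from -0.28 to -0.17 for heat shock (called at -0.28 without untreated replicate 2), 0.017 to 0.11 for oxidative stress (lost at 0.064 without calactin replicate 2, 0.028 without untreated replicate 1 and 0.017 without untreated replicate 3) and -0.18 to -0.12 for the cytoskeleton (called at -0.17 without calactin replicate 1 or untreated replicate 2 and -0.18 without untreated replicate 3).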

Other observations

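The gene families below, all tests on them and the test of the spike scalings were chosen after the result was seen, so the counts and medians of the families alone describe them and test nothing.

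Of 8 genes for E2F factors, which govern entry into S phase, E2F1, E2F2, E2F3 and E2F8 rose, E2F5 fell by 1.14 ± 0.13 (log2, SE, n = 3 each), and the median was 0.49; E2F1 and E2F8 were already among the largest rises. Of 11 genes for the CCR4-NOT complex, which shortens poly-A tails, 5 rose and CNOT11 fell by 0.61 ± 0.08, with a median of 0.25. Under poly-A spike scaling the medians were 1.05 for the E2F factors and 0.805 for the CCR4-NOT genes. CNOT3 rose by 0.93 ± 0.24 and CNOT8, a deadenylase, by 0.51 ± 0.08. CDKN1B, the cyclin kinase inhibitor p27, rose by 1.17 ± 0.11. SPRY2 and SPRED2, which restrain RAS signalling, fell by 2.00 ± 0.29 and 0.97 ± 0.12, ID1 fell by 2.16 ± 0.22 and JUNB fell by 2.55 ± 0.31.

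Of 8 genes for subunits of RNA polymerase I, which transcribes ribosomal RNA, 6 fell and 0 rose, with a median of -0.71 that stayed negative, at -0.15, under poly-A spike scaling. POLR1E fell by 1.79 ± 0.09 and POLR1B fell by 1.11 ± 0.15. Of 12 genes for RNA polymerase II, 1 rose and 2 fell, and of 8 for RNA polymerase III, 1 rose and 2 fell. Genes were assigned by symbol alone, so a subunit shared between polymerases counts only under the one its symbol names. These counts therefore do not compare whole polymerases. Of 14 peroxin genes, 8 fell, PEX3 by 0.70 ± 0.10, with a median of -0.38 that was 0.18 under poly-A spike scaling. Of 15 mitochondrial tRNA synthetase genes, 7 fell, with a median of -0.26 that was 0.30 under poly-A spike scaling. Of 15 cytosolic ones, 2 rose and 6 fell (median -0.17, 0.39 under poly-A spike scaling).

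Of 75 mitochondrial ribosomal protein genes, 42 fell and 4 rose, with a median of -0.38 that was 0.18 under poly-A spike scaling. MRPS26 fell by 1.73 ± 0.14. On these arrays they fell further than genes matched on signal, by a difference of -0.29 ± 0.05 (SE over the arrays, n = 3 each). Of 10000 matched lists, 0% had a median as low (95% of lists from -0.19 to 0). The family was picked after its fall was seen, which favours such a gap, and the matched lists leave out correlation between genes. Whether signal level is the whole cause is therefore not settled by these values. Camera called the family lower with the preset correlation (adjusted p = 2.92e-07 over 11 families). With an estimated correlation the family was not called by camera (adjusted p = 0.278), so whether it stands out among all genes stays open. Compression at the high signals of the cytosolic ribosomal protein genes stays open too: 1.36% of matched lists had as few calls, but those lists had a median signal of 10335 against 13953, so the cytosolic genes cannot be told apart from a saturated measure. A difference between the 2 kinds of ribosome is therefore a hypothesis that these arrays leave open.

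More genes fell than rose, and the scaling of the arrays may account for that balance. On the deposited scale every calactin array had a lower median signal than every untreated one. Under poly-A spike scaling with the replicate block 8.58% of calls were lower, and 69.1% and 74.2% under the hybridisation spike scalings, against 74.0% with the block alone, so scaling and a true excess of falls cannot be told apart while it is unknown how the spikes were added. A loss of short-lived transcripts is a candidate explanation that stays open. Zinc finger genes, whose messenger RNAs are often short-lived, had a median of -0.13 (0.43 under poly-A, -0.03 under hybridisation spike scaling and -0.02 under quantile normalization); 0.65% of 10000 lists matched on signal were as low, but camera did not call them (adjusted p = 0.229; adjusted p = 0.814 with an estimated correlation), and of 466 genes 81 fell, 16 rose and 369 were not called. Among 32 immediate early genes, many of them short-lived, 10 fell, 1 rose and 21 were not called, such as JUN at 0.23 ± 0.13 and ATF3 at 0.08 ± 0.11.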
